A study of Mus musculus with 9 samples.

How the data were processed

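The series profiled helper T cells of mice by CITE-seq, in which RNA and antibody-derived tags are read from the same droplets. Each of 3 pools of cells had a gene expression library, a library of antibody tags and a T cell receptor library, which makes 9 samples. The antibody tags used here were hashtags, oligonucleotide-tagged antibodies that mark which cells of a pool came from which sorted population. One pool held wildtype cells from LCMV Armstrong or LCMV Docile infection, taken from spleen and lymph nodes. The other pools held splenic cells of mixed bone-marrow chimeras with LCMV Docile, 1 pool for a conditional deletion of Eomes and 1 for a conditional deletion of Myb. The receptor libraries were not analysed here.

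The deposited values are counts of unique molecular identifiers (UMIs) for each gene or hashtag and each cell barcode, not normalized. They were made by the authors with Cell Ranger 7.0.0, per the file headers, against mm10, per the submitters' processing notes. The annotation release, the cell calling and any filter before deposit were not given in the sources used here. Each matrix held 32285 genes, and hashtag and gene counts of a pool were in the same matrix.

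Cells with fewer than 500 detected genes (364, 113 and 310 in the wildtype, Eomes and Myb pools) and then cells with more than 10% mitochondrial UMIs (199, 88 and 76) were removed. This left 27512 of 28075, 25776 of 25977 and 28747 of 29133 barcodes. For each hashtag a mixture of 2 normal distributions was fitted to log10(UMIs + 1) (scikit-learn 1.9.0), and a cell was positive where the posterior of the upper component was at least 0.5. Cells positive for 1 hashtag were kept as singlets (21464, 21290 and 22856). Cells positive for more than 1 hashtag (5956, 4388 and 5699, or 21.6%, 17.0% and 19.8%) and for none (92, 98 and 192) were left out. Doublets of cells with the same hashtag cannot be seen this way, and from the multiplet rate and the hashtag shares they were estimated at 4.94%, 10.5% and 14.3% of the singlets. Scrublet, run through scanpy 1.11.5, marked 0, 2 and 0 cells at its own threshold and therefore had not worked. An alternative that left out cells scoring above the median of the hashtag multiplets was added after the data were examined.

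A hashtag was given to a group only where its deposited name states the genotype and gate. In the Eomes pool these were control cells (Cd4cre) sorted as CD44+PD1+, control cells with the added gate CD62L+, and Eomes knockout cells sorted as CD44+PD1+. The Myb pool had the same arrangement, with control cells named WT by the hashtags and Mybfl/fl by the sample labels. The 7 hashtags of the wildtype pool, HT1 to HT7, are named by number only. They were left unassigned, so Docile was not compared with Armstrong, and their values are given as ranges and medians. Each group therefore held 1 hashtag sample, called a library here although the hashtags of a pool share 1 gene expression library, so no p-value was computed for a difference between groups and no gene was called changed. Counts of genes at least 2-fold apart describe size only. The comparison of the CD62L+ gate with the full gate was added after the hashtag names were seen. The comparison of Eomes and Myb between clusters had been designed with a mean over hashtags and an edgeR test, a test within samples that needs no assignment. It was left out, because samples without a stated group are given here as ranges and medians only.

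UMIs were summed per hashtag and divided by the library total to give counts per 1e6 library UMIs (CPM). A gene's log2 ratio between 2 libraries was given with an exact 95% interval conditional on the sum of both counts, a CPM value with an exact Poisson interval and a share of cells with a Clopper-Pearson interval. These intervals cover counting error only, not differences between animals or sorts. A gene at 0 in 1 library was set to 3 counts. TMM factors (edgeR 4.0.16, R 4.3.3) were the alternative scaling. They moved the median log2 ratio of genes at 20 CPM or more from −0.185 (6106 genes) to 0.0224 (6130 genes) in the Eomes knockout comparison and by less than 0.1 in the others. For the Eomes knockout, log2 ratios are therefore given relative to the median gene. For the Myb pool and the gates they are plain log2 ratios of CPM.

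The named genes followed a rule fixed before the data were examined: the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 20 CPM and at least 100 UMIs over both libraries, then Eomes and Myb, then up to 4 members of each list by the size of the log2 ratio at 20 CPM or more. Receptor and immunoglobulin segments, Xist, Y-linked and mitochondrial genes were not named. Between 62 and 68 such genes reached 20 CPM per comparison, and 12 differed at least 2-fold in the Eomes knockout comparison, 7 in the Myb comparison, and 7 and 3 in the gate comparisons of the Eomes and Myb pools. For the gates the mean of both pools' log2 ratios was ranked, a choice made after the data were examined. List members that make up a count of 5 or fewer are also named, and so are genes that lead a cluster or differ most in range over the unassigned hashtags; these were chosen after their values were seen. Not every gene that the rule names is given in the text: some were left out for reasons unrelated to their values.

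The 26 lists were also fixed beforehand. The 15 marker lists were Th1, Tfh (follicular helper), stem-like, Treg (regulatory), cycling, interferon-responsive, cytotoxic, CD8 T, NK or innate-like T, B, plasma, myeloid, erythroid or platelet, Th17 and Th2. The other 11 were exhaustion and inhibitory receptors, T cell receptor (TCR) signal response, cytokines and helper ligands, lymphoid homing and egress, effector migration, survival, glycolysis, oxidative phosphorylation, T cell transcription factors, dissociation stress and ribosomal proteins. Some genes stand in more than 1 list. The survival list held 1 name, Bim, that is no symbol in the files. A member was counted as measured from a mean of 5 CPM, and a list with fewer than 3 measured members got no median; this floor was set after the data were examined. A list's median was given its percentile among 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean expression. Members were counted above or below the median gene of the comparison.

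Cells were clustered per pool on 2000 variable genes, leaving out Eomes, Myb, receptor and immunoglobulin segments, Xist and Y-linked genes. Counts were scaled to 10000 per cell, log-transformed and reduced to 30 principal components, and a shared-neighbour graph of 15 neighbours was split by Leiden at resolution 0.6 (igraph 0.11.9). Clusters were named from the fixed markers by a rule set after the data were examined. At least 2 of the 10 leading genes had to come from the named list, more than from any other of the 15 marker lists. At least 3 of its markers had to stand at 20 CPM or more. Leading genes were those at 20 CPM or more with the highest ratio to the other cells of the pool. A cluster that the B, plasma, myeloid or erythroid list would have named although its CD3 and Trac level was at least 0.5 of the pool's, or that was led by the granule genes Mpo, Elane, Prtn3 or Ctsg, stayed unnamed. A cluster led by Sox4 and Slamf7 in each pool matched none of the fixed lists and was followed under those genes' names. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs and leaving out shallower cells.

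The singlets of a chimera library held between 24640604 and 63821289 gene UMIs, and those of HT1 to HT7 between 5913337 and 16531508. The ratio and list steps were tested on simulated libraries drawn from the control libraries, with 200 genes altered by known folds. For the Eomes knockout comparison (6326 genes) the intervals held the true value for 91% of 2-fold and 98% of 1.5-fold genes and for 95.5% of unaltered genes. Of 100 unaltered lists of 12 genes, 8 fell outside percentiles 2.5 to 97.5. For the Myb comparison (6278 genes) these values were 93%, 94%, 94.9% and 5. A list altered 2-fold reached percentile 100 in both. The simulated counts of each gene were drawn independently. They therefore do not show how often a list whose members vary together reaches an extreme percentile, nor cover differences between animals or sorts.

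The alternatives tried were TMM scaling, HTODemux calls (Seurat 5.3.0, positive quantile 0.99), a rule that the top hashtag be at least 5 times the second after dividing by each hashtag's median, T cell clusters only, Treg-like or cycling-like cells left out, and stricter cells (at least 1000 genes and at most 5% mitochondrial UMIs). For shares they were Leiden resolutions 0.4 and 1, 1000 variable genes, and thinning before clustering. The ratio rule after dividing by each hashtag's background, and leaving out cells with haemoglobin UMIs, were added after the data were examined. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.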

Results

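Helper T cells of mice infected with LCMV were collected 28 days after infection as 3 pools, each with gene expression, antibody tag and T cell receptor libraries (9 samples). The wildtype pool held PD1+CD4+ cells of LCMV Armstrong or LCMV Docile infection from spleen and lymph nodes. Its cells fell into 7 hashtag samples that are not assigned to a virus or tissue. The other pools held splenic cells of mixed bone-marrow chimeras with LCMV Docile. The Eomes pool held control cells, control cells of a CD62L+ gate and cells labelled Eomes knockout. The Myb pool held the same populations for a conditional deletion of Myb, with control cells named WT by the hashtags and Mybfl/fl by the sample labels. Each group was 1 hashtag sample, and the cells of a hashtag, which share the gene expression library of their pool, are called a library below.

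After filtering, 8194 control, 6922 CD62L+ and 6174 knockout cells remained in the Eomes pool, with a median of 3918, 4688.5 and 5653.5 UMIs per cell. In the Myb pool 5856 control, 10874 CD62L+ and 6126 knockout cells remained, with medians of 3835, 4865 and 3653 UMIs. The wildtype samples HT1 to HT7 held 3820, 3547, 3443, 3111, 3015, 3143 and 1385 cells, with medians of 3650.5, 4120, 3781, 3360, 3809, 4073 and 3924 UMIs.

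The targeted genes encode transcription factors of T cells. Eomes (ENSMUSG00000032446) lies on chromosome 9 at 118478186 to 118486132 of mm10, and Myb (ENSMUSG00000019982) on chromosome 10 at 21124930 to 21160984. Eomes was read at 41.8 CPM (39.7 to 43.9) in control cells of the Eomes pool, at 115 CPM in CD62L+ cells and at 3.15 CPM (2.62 to 3.74) in the knockout library. In the Myb pool Eomes stood at 48.1, 142 and 29.95 CPM in control, CD62L+ and knockout cells. In HT1 to HT7 it stood at 39.2, 16.9, 15.8, 65.3, 65.6, 104 and 63.1 CPM.

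Myb was not lower in the library labelled Myb knockout. It was read there at 69.0 CPM (65.8 to 72.4), against 40.5 CPM (38.0 to 43.1) in control cells and 123 CPM in CD62L+ cells. In the Eomes pool Myb stood at 31.6, 102 and 34.5 CPM in control, CD62L+ and knockout cells, and in HT1 to HT7 at 46.7, 31.6, 27.7, 33.1, 41.2, 82.3 and 57.3 CPM. The label does not name the deleted exon and the reads come from the 5' end of transcripts, so a Myb read outside that exon checks nothing. Directions drawn from this library below therefore rest on its label alone.

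**Figure D1:**
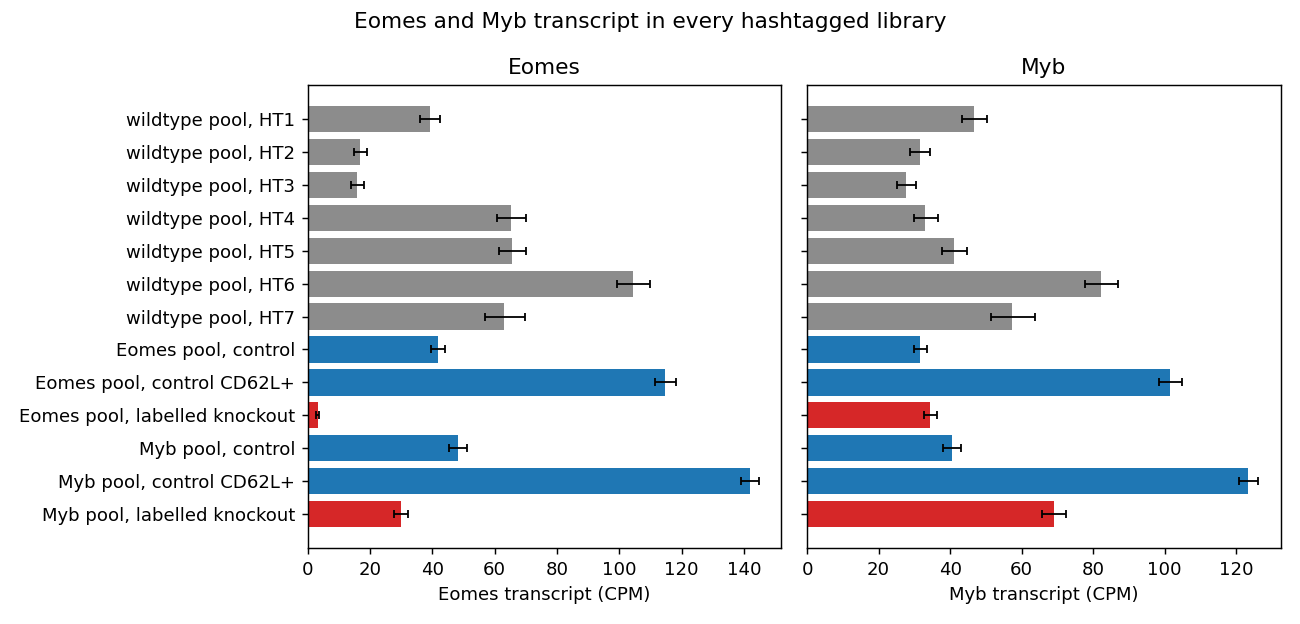
Eomes and Myb in CPM in each of the 13 hashtag libraries, with wildtype samples in grey, chimera controls in blue and labelled knockouts in red; bars are exact Poisson intervals that cover counting error only. Eomes is lowest in the Eomes knockout library (3.15 CPM).

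In the library labelled Eomes knockout, genes of cytotoxic and follicular helper cells stood far below the control and genes of the stem-like list stood above it. The chemokine gene Ccl4 and the granzyme gene Gzmk were nearly absent, as was Tox2, a transcription factor gene of follicular helper cells. Ccr7, which encodes a chemokine receptor of cells that enter lymph nodes, was higher. The Treg factor Foxp3 and the inhibitory receptor gene Tigit were lower. Values below are log2 ratios relative to the median gene, because the median of all genes lay at −0.185 under plain scaling and at 0.0224 under TMM scaling.

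The targeted gene Eomes differed by −3.55 (−3.82 to −3.28) and Myb by 0.31 (0.19 to 0.42). Under plain scaling the ratio of Eomes was −3.73, and −2.70 with HTODemux hashtag calls. The highest genes were Edn3, an endothelin gene (4.81, 4.64 to 4.996; 180 against 7.25 CPM), and Stfa3, a stefin gene (4.73, 4.60 to 4.85; 352 against 15.1 CPM). Lratd1 (3.63), Atp8b4 (3.42), the cytokine signalling inhibitor Socs2 (3.25), Apobec2 (3.25), Gstm1 (3.24) and Ifitm10 (3.22) came next. Dpysl3 (2.86), Ckb (2.85), Ildr1 (2.85) and C2cd4b (2.75) completed the highest genes. The lowest genes included Ccl4 (−6.65, −7.06 to −6.26; 1.35 against 154 CPM), Cebpa (−5.96), Gm30211 (−5.89) and Apoe (−5.77). Tox2 (−5.29; 3.12 against 139 CPM), the follicular helper gene Sostdc1 (−5.03; 17.8 against 659 CPM), Ier5l (−4.96), Padi4 (−4.57), Gzmk (−4.42; 4.23 against 103 CPM) and Ccl3 (−4.37) followed. The haemoglobin genes Hbb-bt (−7.34) and Hbb-bs (−7.01) had the lowest ratios among genes at 20 CPM or more, with Hbb-bs at 246 CPM in the control and 1.67 CPM in the knockout library. Leaving out cells with any haemoglobin UMI kept 8091 of 8194 control cells, so these ratios rest on few control cells.

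The cytotoxic list had a median of −2.86 (percentile 0 among matched random lists), with 7 of 9 measured genes at least 2-fold lower, among them Gzmb (−3.60) and Ccl5 (−2.86; 145 against 1196 CPM), and only Nkg7 and Crtam above the median gene. Th1 genes were split around a median of −1.27 (percentile 0). At least 2-fold lower were 8 of 13 genes, Il18r1 (−2.72) and Ifng (−2.27) among them, whereas Ly6c2 (400 against 105 CPM), Tbx21, the gene of the Th1 factor T-bet (87.6 against 35.7 CPM), Nkg7 (716 against 371 CPM), Cxcr6 (1.02) and Id2 (240 against 168 CPM) were above. The effector migration list lay at −0.67 (percentile 0), with Ccr8 (−3.40) and Selplg (−1.02) lower and only Cxcr6 and Itgb1 above.

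The Tfh list lay at −1.74 (percentile 0), with 10 of 13 genes at least 2-fold lower, including Ascl2 (−3.66) and Il4 (−2.57), and Cd200, Izumo1r and Angptl2 above. The Th2 list, which also holds Il4, lay at −2.57 (percentile 0), with Ccr4 lower and Gata3 higher (0.57). Among helper cytokines (−0.10, percentile 13.2) Il21 (−1.74), Ifng and Il4 were at least 2-fold lower, Cd40lg stood at −0.86, and Il2, Csf1, Tnfsf8 and Lta were above. The transcription factor list was split at −0.28 (percentile 0), with 11 of 20 genes below and 9 above the median gene. Runx3 (−3.18), Bcl6 (−2.25) and Maf (−1.68) were among the lower and Batf, Tbx21 and Id3 (1.204) among the higher. Exhaustion and inhibitory receptor genes lay at −0.69 (percentile 0.01). Tigit (−3.32; 37.1 against 422 CPM), Ctla4 (−2.78) and Entpd1 were at least 2-fold lower, Pdcd1 (−0.96; 217 against 479 CPM) and Nt5e (−0.91) were lower, and Btla, Nr4a2, Tox and Cd160 were above.

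The stem-like list lay at 0.75 (percentile 100), with 11 of 14 genes above the median gene. Dapl1 (2.39), Ccr7 (1.98; 224 against 64.8 CPM), Id3 and Bach2 were at least 2-fold higher, and Satb1, Ly6c1 and Ltb were below. In the homing list (0.12, percentile 84.4) higher Ccr7 stood beside lower Cxcr4 (−1.13), Gpr183 (−0.93), Itgb7 and S1pr4. Survival genes (0.12, percentile 84.7) were split, with Bcl2 (0.91), Il7r (0.81), Birc3, Bcl2l1 and Mcl1 above and Pim1 (−1.30), Bcl2l11, Bcl2a1d and Bcl2a1b below. TCR signal genes (0.08, percentile 84.9) were split as well, with Irf8 (1.86) and Myc (1.34) above and Egr2 (−0.42) below.

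The Treg list lay at −0.43 (percentile 0), with Foxp3 (−3.39; 6.86 against 81.7 CPM), Ctla4, Ikzf2 (−1.57) and Tnfrsf9 (−1.09) at least 2-fold lower and Nrp1 and Capg above. Without Treg-like cells in both libraries its median turned to 0.11. Cycling genes (−0.58, percentile 0.01) such as Mki67 (−0.95) and Rrm2 (−0.89) were lower, with only Top2a above. Interferon-responsive genes (−0.19, percentile 0.81) were mostly lower, Ifit3b (−0.72) among them, with Isg20 (0.73) and Oasl2 above. Glycolysis genes lay at −0.16 (percentile 0.98; Tpi1 −0.66, Slc2a1 −0.61; above Gpi1, Ldha and Hk1). Oxidative phosphorylation genes lay at 0.12 (percentile 68.0; Uqcrh 0.54; below Sdhb only).

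Ribosomal protein genes lay at 0.61 (percentile 100), with 83 of 88 above, such as Rps12 (0.93) and Rps19 (0.90); the 5 below were Rps6ka1, Rps6ka4, Rps6kb1, Rps6kb2 and Rps19bp1, which do not encode ribosomal proteins. Dissociation stress genes lay at −0.21 (percentile 0.19; Fos −1.07, Jun −0.52; above Ier2, Hspa1a, Egr1 and Hspa1b). Markers of other cell types also differed. The erythroid list (Hbb-bt, Hba-a1 and Hbb-bs) lay at −7.05 (percentile 0), the plasma list at −1.80 (percentile 0.11; Igkc −4.13, Xbp1 −0.52 and Jchain) and the B list at −1.28 (percentile 0.33; Ighm −3.40 and Cd74 −1.28 lower, H2-Eb1 above). Ighm was read at 25.0 CPM in the knockout library and 300.5 CPM in the control. The CD8 T, NK, myeloid and Th17 lists had 1, 1, 2 and 0 measured genes. No replicate checks these differences.

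**Figure D2:**
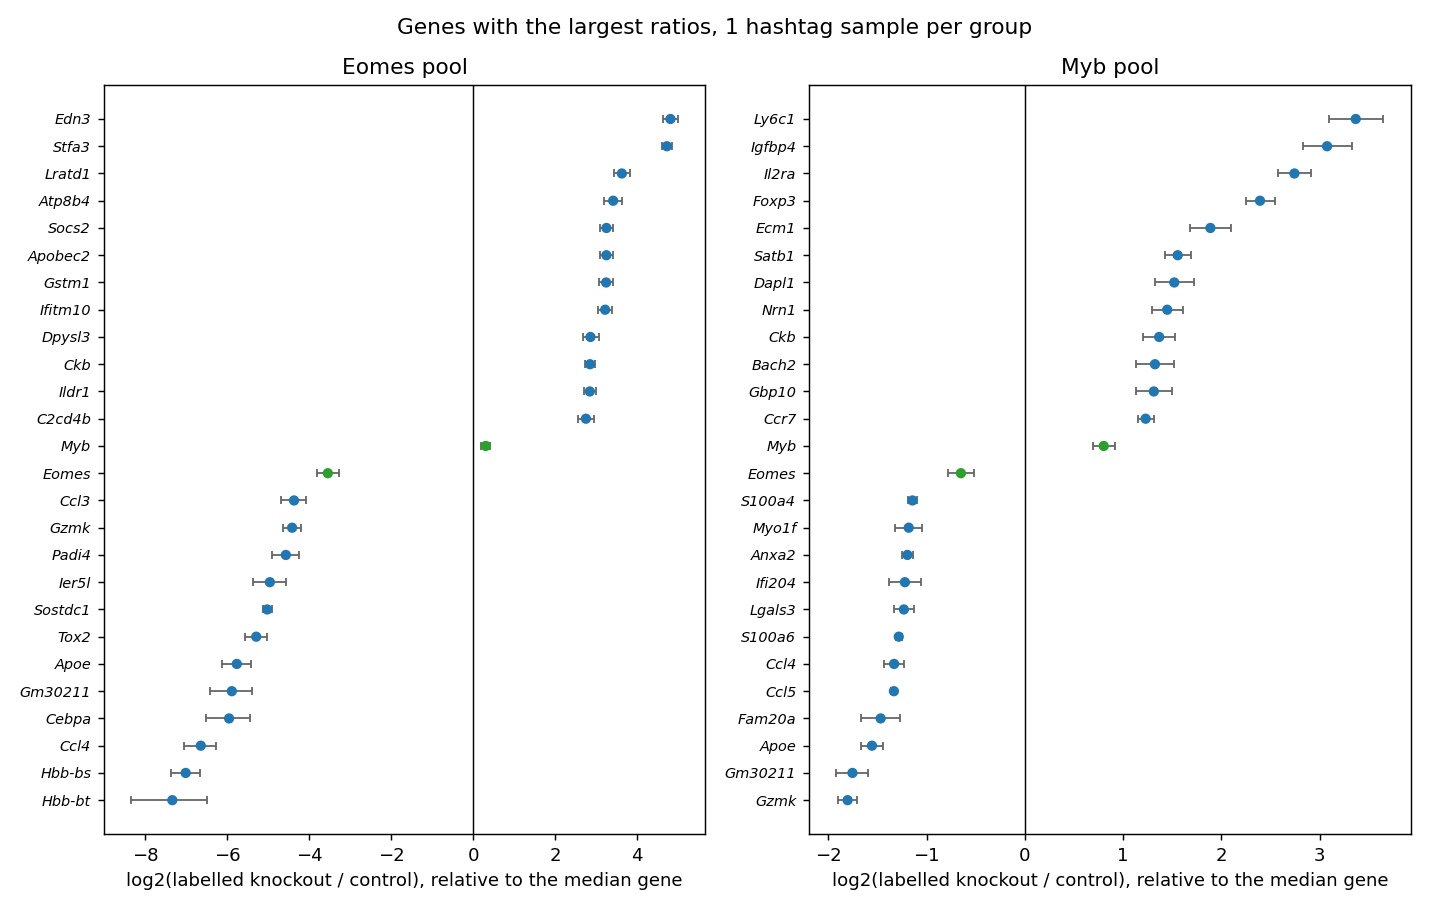
Log2 ratio of the labelled knockout over its control, relative to the median gene, for the 12 highest and 12 lowest genes of each chimera pool with Eomes and Myb in green; bars are intervals that cover counting error only. Ccl4 stands at −6.65 in the Eomes pool.

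Most knockout cells of the Eomes pool lay in a single cluster, cluster 0, which held 81.4% (80.4 to 82.4) of that library against 0.671% of control and 1.34% of CD62L+ cells. It is in large part that library, so its leading genes, Edn3 and Stfa3, are not taken as a cell type. Few knockout cells fell into the Treg-like, Tfh-like and cytotoxic-like classes, but class shares do not count such cells within cluster 0. Il21, among the 10 of 13 Tfh genes at least 2-fold lower, was read in 5.62% of knockout and 16.8% of control cells after thinning. That gap was far smaller than the gap in Tfh-like shares. Tfh-like cells made up 14.8% (14.0 to 15.5) of control and 0.0810% (0.0263 to 0.189) of knockout cells, and cytotoxic-like cells 4.65% and 0.0486% (0.01002 to 0.142). Stem-like cells made up 1.43% (1.18 to 1.71) and 0.923% (0.700 to 1.195), although the stem-like list was higher in the knockout library, most of whose cells lay in cluster 0. Cycling-like cells made up 2.58% and 1.77% and interferon-responsive cells 3.23% and 4.31%. The last difference turned under 2 alternatives, but in 1 of them, with strict cells, the class held other cells. The cluster led by Sox4 and Slamf7 held 1.66% and 1.70%, but its knockout cells had far less of the genes that name it (Sox4 97.4 against 401 CPM, Slamf7 18.5 against 690 CPM), so these shares do not compare the same cells.

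Foxp3 was read in 10.4% (9.68 to 11.1) of control and 1.01% (0.774 to 1.302) of knockout cells after thinning, with 727 and 251 shallow cells left out (15.1% and 2.61% unthinned). Tfh-like control cells gave 1.498% (0.875 to 2.39), and the knockout share was not above theirs. Foxp3 was not left out of the clustering, and it was not tested whether Tfh-like cells lack it, so their share is not a known background. Treg-like control cells gave 48.3%. The median depth was 3980 UMIs in the Tfh-like cluster and 4070 and 4506 in the Treg-like clusters. The Treg-like class made up 17.6% (16.8 to 18.4) of control and 1.15% (0.899 to 1.45) of knockout cells. Its cells lay mostly in a Klrg1- and Ccr8-led cluster in the control (929 and 513 cells) and in an Il2ra- and Gpr83-led cluster in the knockout library (4 and 67 cells).

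Clusters outside the classes also differed. Cluster 1, led by Hbb-bs, Hbb-bt, Il21, Lgals3 and Sostdc1, held 25.9% of control, 10.1% of CD62L+ and 0.421% of knockout cells. Few of its 2124 control cells held haemoglobin, since 8091 of all 8194 control cells had no haemoglobin UMI. Cluster 2, led by Rflnb and Lmo4, held 21.2%, 12.5% and 1.02%. Cluster 5, of low depth and led by Slpi, Jchain and nuclear RNAs, held 5.94%, 7.17% and 4.34%. Cluster 12, led by Spp1, Irf8 and Serpina3f, held 0.122%, 0.0289% and 2.59%. Cluster 13, led by the granule genes Mpo and Elane, held 0.269%, 0.896% and 0.211%.

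In the library labelled Myb knockout, genes of the stem-like and Treg lists stood above the control, while genes of the cytotoxic and effector migration lists stood below it. Ly6c1, a surface gene of naive-like cells, and Il2ra, which encodes the high-affinity IL-2 receptor chain, were among the highest. The granzyme gene Gzmk and the chemokine genes Ccl5 and Ccl4 were among the lowest. Myb itself was not lower, so these directions rest on the label of the library.

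Myb differed by 0.77 (0.66 to 0.88; 0.48 with HTODemux hashtag calls and 0.45 with the ratio to hashtag medians) and Eomes by −0.68 (−0.82 to −0.55). The highest genes were Ly6c1 (3.33, 3.07 to 3.61; 50.4 against 4.99 CPM), Igfbp4 (3.04), Il2ra (2.71, 2.55 to 2.88; 90.6 against 13.8 CPM), Foxp3 (2.36, 2.21 to 2.51; 93.6 against 18.2 CPM) and Ecm1 (1.86). Satb1, a chromatin organizer gene of naive cells (1.52), Dapl1 (1.49), Nrn1 (1.42), Ckb (1.33), the repressor gene Bach2 (1.29), Gbp10 (1.28) and Ccr7 (1.196; 167 against 72.9 CPM) followed. The lowest were Gzmk (−1.84, −1.93 to −1.74; 46.4 against 166 CPM), Gm30211 (−1.79), Apoe (−1.59), Fam20a (−1.50), Ccl5 (−1.37; 662 against 1707 CPM) and Ccl4 (−1.36). S100a6 (−1.32; 549 against 1368 CPM), Lgals3 (−1.26), Ifi204 (−1.25), Anxa2 (−1.23), Myo1f (−1.22) and S100a4 (−1.18) completed them.

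The cytotoxic list lay at −0.53 (percentile 0), with Gzmk, Ccl5, Ccl4 and Gzma at least 2-fold lower, Ccl3 (−0.81) lower and only Klrd1 (1.17) above. The Th1 list lay at −0.40 (percentile 0), with Ccl5 at least 2-fold lower, Il18r1 (−0.95), Cxcr6 (−0.78) and Nkg7 (−0.40) lower and only Tbx21 above. With T cell clusters only, these medians were −0.84 and −0.68. Effector migration genes lay at −0.52 (percentile 0; Itgb1 −0.67, Cxcr3 −0.56; above Itgae 2.54 and Ccr8). Homing genes lay at −0.32 (percentile 0; Cxcr4 −0.66, S1pr1 −0.57, Klf2 −0.46), with Ccr7 above.

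The Tfh list lay at −0.47 (percentile 0), with Il4 (−1.15) and Pou2af1 (−1.06) at least 2-fold lower, Ascl2 (−0.99) and Tox2 (−0.64) lower, and Izumo1r and Cd200 above. The Th2 list lay at −0.19 (percentile 4.06; Il4, Ccr4 and Gata3 −0.19, all below). Helper cytokine genes lay at −0.28 (percentile 0.03; Il21 −0.52, Ifng −0.39; above Lta 0.50 and Csf1). The transcription factor list lay at −0.18 (percentile 0.07), with Bcl6 at −0.60 and Satb1 and Bach2 at least 2-fold higher. Exhaustion genes were split (−0.08, percentile 25.5). Pdcd1 (−0.79), Tigit (−0.49), Tox (−0.43), Nr4a2 and Btla were below, and Cd160 (0.74), Ctla4, Entpd1, Nt5e and Lag3 were above.

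The stem-like list lay at 0.29 (percentile 100), with Ly6c1, Satb1, Dapl1, Bach2 and Ccr7 at least 2-fold higher and S1pr1, Klf2, Slamf6, Id3 and Tcf7 (−0.17) below. The Treg list lay at 0.29 (percentile 100), with Il2ra, Gpr83 and Foxp3 at least 2-fold higher, Tnfrsf9 (0.82) and Ctla4 (0.30) above and only Ikzf2 below. Without Treg-like cells its median was 0.006. TCR signal genes lay at 0.24 (percentile 100; Myc 0.99, Cd69 0.49; below Nfatc1, Egr2 and Nfkbid). Survival genes were split (−0.04, percentile 55.8), with Il7r (0.35), Birc3, Mcl1 and Pim1 above and Bcl2, Bcl2l1, Bcl2l11, Bcl2a1b and Bcl2a1d below.

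All 10 cycling genes were below the median gene (−0.40, percentile 0; Mki67 −0.56, Rrm2 −0.52), and so were 10 of 11 interferon-responsive genes (−0.30, percentile 0; Oasl2 −0.49, Ifit3b −0.45; above Usp18). Glycolysis genes lay at −0.21 (percentile 0.13; Tpi1 −0.35; above Slc2a3) and oxidative phosphorylation genes at −0.08 (percentile 42.6; above Uqcrh, Atp5g1 and Atp5b). Ribosomal protein genes lay at 0.18 (percentile 100; Rps20 0.33), with Rps6ka5, Rps6ka4, Rps6ka1, Rps27l and Rps6kb2 below. Dissociation stress genes lay at 0.10 (percentile 99.8; Fosb 1.19, Jun 0.91, Fos 0.77), with only Hspa1b and Hspa1a below. Among markers of other cell types, the plasma list lay at −0.18 (percentile 4.6), with Igkc (−1.08) and Xbp1 lower and Jchain 6.17 higher (37.9 against 0.528 CPM). The CD8 T, NK, B, myeloid, erythroid and Th17 lists had 1, 1, 2, 2, 0 and 2 measured genes. These differences have no replicate check either.

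The Treg-like class made up 21.0% (19.95 to 22) of the library labelled Myb knockout and 7.48% (6.82 to 8.18) of its control, mostly in 1 cluster led by Foxp3 and Il2ra (1263 and 406 cells). Foxp3 was read in 12.2% (11.3 to 13.1) and 3.37% (2.90 to 3.89) of cells after thinning, with 983 and 600 shallow cells left out (16.9% and 5.33% unthinned). Tfh-like cells gave 2.15% (1.44 to 3.07) in the knockout library and 1.40% (0.945 to 1.99) in the control, Treg-like cells 42.4% and 26.5%. Median depth was 3996 UMIs in the main Treg-like cluster and 4622 and 3517 in the Tfh-like clusters.

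Tfh-like cells made up 23.9% (22.8 to 24.9) of the library labelled Myb knockout and 39.0% (37.8 to 40.3) of its control; 1 of the 2 Tfh-like clusters was also led by the TCR signal genes Nr4a1, Nfkbid and Irf4. Stem-like cells made up 12.1% (11.3 to 12.9) and 10.7% (9.88 to 11.5). In the control they lay mostly in an Il7r- and Klf2-led cluster (604 and 20 cells), in the knockout library also in an Igfbp4- and Ly6c1-led cluster (443 and 298 cells). Cytotoxic-like cells made up 1.78% and 5.06%, cells led by Sox4 and Slamf7 0.408% (0.264 to 0.602) and 1.54% (1.24 to 1.89), cycling-like cells 0.931% and 1.40%, interferon-responsive cells 2.27% and 3.93%, and NK-like cells 2.35% and 1.66%. Of the clusters outside the classes, cluster 8, led by Lgals3, S100a6, S100a4 and Il10, held 0.979% and 6.28%. Cluster 13, of low depth and led by Jchain, Slpi and Mzb1, held 3.64% and 1.88%, and 0.533% of CD62L+ cells. Cluster 0 held 20% and 15.5%, and cluster 6 held 10.7% and 5.67%.

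**Figure D3:**
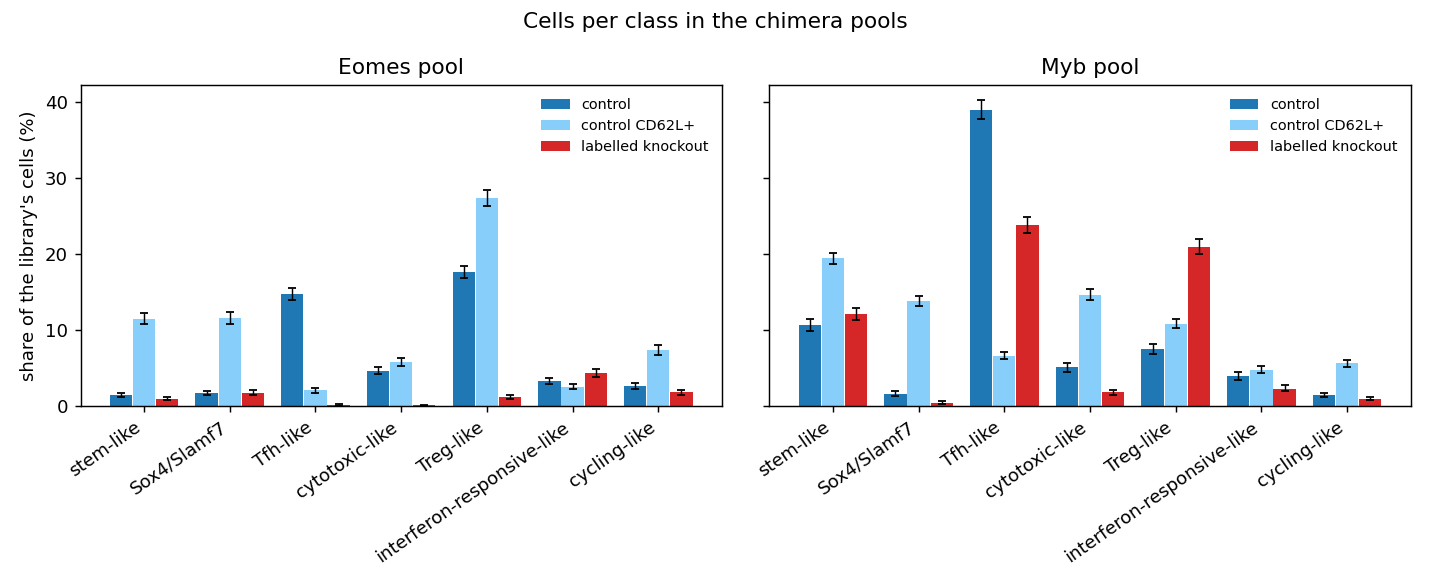
Percent of cells in each class for the control, CD62L+ and knockout libraries of the Eomes and Myb pools; bars are exact binomial intervals that cover counting error only. Treg-like cells make up 1.15% of the Eomes knockout library and 21.0% of the library labelled Myb knockout.

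Cells of the CD62L+ gate were compared with the full gate among control cells of both pools. CD62L+ cells had more Myb and Eomes, more of the transcription factor gene Sox4 and of Slamf7, an adhesion receptor gene, and more granzyme B transcript. Genes of follicular helper cells and of B cell help, such as Ascl2, Il4 and Il21, were lower.

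The highest genes were Sox4 (2.49 in the Eomes pool, 2.32 in the Myb pool), Dapl1 (1.93, 1.72), Slamf7 (1.86, 1.76), Tm6sf1 (1.66, 1.93), Ly6c2 (1.68, 1.66), Myb (1.68, 1.61) and Eomes (1.46, 1.56). Bach2 (1.31, 1.59), Itm2a (1.301, 1.59), Gzmb (1.14, 1.63) and Crtam (1.45, 1.31) followed. The lowest were Apoe (−2.61, −4.79), Sostdc1 (−2.95, −3.34), Ascl2 (−2.91, −3.35), Padi4 (−2.63, −3.05), Il4 (−2.63, −2.82), Fam43a (−2.44, −2.95) and Gm30211 (−2.37, −2.11). Ctsl (−1.98, −2.48), Gm14718 (−2.15, −2.11), Cebpa (−1.94, −2.20), Asb2 (−1.59, −2.34) and Il21 (−1.92, −1.63) completed them. Across 9236 genes the log2 ratios of the pools correlated at 0.918.

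By list, Tfh genes lay at −1.52 and −1.51 and helper cytokine genes at −1.29 and −1.09 (percentile 0 each), with Pou2af1 the only Tfh gene above in the Eomes pool. Cycling genes lay at 1.25 and 1.19, cytotoxic genes at 0.63 and 1.03, stem-like genes at 0.48 and 0.59 and homing genes at 0.26 and 0.42 (percentile 100 each). In the stem-like list Tcf7, Slamf6, Ltb, Id3 and Il7r were below the median gene in both pools. Among cytotoxic genes only Ccl3 and Ccl4 were below, in the Eomes pool. Th1 genes lay at 0.15 and 0.51 (percentiles 99.9 and 100), exhaustion genes at −0.45 and −0.55 and transcription factors at −0.42 and −0.42 (percentile 0 each).

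Treg genes lay at 0.11 and −0.03 (percentiles 96.6 and 57.0), and effector migration genes at 0.26 and −0.16 (99.95 and 7.31), a sign that differed between pools and turned in the Eomes pool without Treg-like cells. Glycolysis genes lay at −0.27 and −0.25 (percentiles 0.03 and 0.08), stress genes at −0.23 and −0.24 (0.18 and 0.13) and ribosomal protein genes at 0.16 and 0.13 (100 each). Interferon-responsive genes lay at −0.09 and −0.05 (18.4 and 40.9), TCR signal genes at −0.13 and −0.04 (16.9 and 60.3), oxidative phosphorylation genes at 0.04 and 0.03 (79.6 and 61.2) and survival genes in the Eomes pool at −0.05 (percentile 51). Th2 genes lay at −0.25 and −0.33 (6.11 and 1.71) and B genes at 0.51 and −0.08 (99.6 and 40.9). In the Eomes pool alone the erythroid list lay at −5.89 (percentile 0), the NK list at 1.36 (99.97) and the plasma list at −0.02 (67.7). Neither pool had a replicate for this gate.

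By class, cells led by Sox4 and Slamf7 made up 11.6% of CD62L+ cells in the Eomes pool and 13.8% in the Myb pool, against 1.66% and 1.54% of the full gate. Stem-like cells made up 11.5% and 19.4%, against 1.43% and 10.7%. Tfh-like cells made up 2.02% and 6.60%, against 14.8% and 39.0%, and Treg-like cells 27.4% and 10.8%, against 17.6% and 7.48%. The stem-like and Tfh-like classes held more clusters in the Myb pool, so their shares do not compare the same cells between pools. In the Myb pool the stem-like cluster led by Igfbp4 and Ly6c1, as in the Eomes pool, held 3.51% of CD62L+ cells, against 0.342%. The Tfh-like cluster led by Apoe and Padi4, as in the Eomes pool, held 0.745%, against 22.8%.

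Among the genes named by size, Ckb was among the highest in both knockout comparisons, and Gm30211, Apoe, Ccl4 and Gzmk were among the lowest in both. Of the 5986 genes that could be named in both, the highest included 1 for Eomes and 8 for Myb, so at most 1 could be shared, and the lowest included 10 and 11. By chance 0.00134 and 0.0184 shared genes would be expected if genes were independent, which they are not. Across 9135 genes the log2 ratios of the knockout comparisons correlated at 0.273 (rank correlation 0.212). The Eomes knockout ratios correlated with the gate ratios of the Myb pool at 0.235, and the ratios of the library labelled Myb knockout with the gate ratios of the Eomes pool at 0.258. Foxp3 and the Treg list had opposite signs in the knockout comparisons, lower for Eomes and higher for the library labelled Myb knockout.

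In the wildtype pool a cluster led by Sox4, Slamf7 and Ly6c2 (896 cells) had high levels of both Eomes and Myb, although neither gene was used to build the clusters. A cluster of low depth led by nuclear RNAs also had raised levels of both (91.0 and 167 CPM). Cytotoxic-like cells had high Eomes, with Myb close to the level of other cells. Stem-like, Treg-like and Tfh-like cells had lower medians of both. The stem-like class joined a cluster led by Igfbp4, Ly6c1 and Dapl1 (3432 cells) and a cluster led by Il7r, Itgb1 and Rflnb (3345 cells). Its marker list holds genes of naive cells, such as Ly6c1 and Satb1. The class name therefore does not set stem-like cells apart from naive-like ones.

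In the Sox4 and Slamf7 cluster Eomes ranged from 261 to 362 CPM over HT1 to HT7 (median 331), against a median of 38.3 CPM in the other cells of a sample. Myb ranged from 256 to 427 CPM (median 353), against 30.4 CPM. Both genes were above the other cells in 7 of 7 samples (median log2 3.11 and 3.15). In cytotoxic-like cells Eomes ranged from 278 to 376 CPM (median 324) and Myb from 32.9 to 87.6 CPM (49.4, against 40.3 in the other cells and above them in 6 of 7 samples). In stem-like cells Eomes ranged from 5.90 to 20.7 CPM (9.76) and Myb from 16.3 to 23.9 CPM (18.7), both below the other cells in all samples (median log2 −2.70 and −1.50). Treg-like cells had medians of 7.91 CPM Eomes and 18.3 CPM Myb, Tfh-like cells 13.9 and 19.5, cycling-like cells 17.7 and 49.4, interferon-responsive cells 23.6 and 19.4 and NK-like cells 132 and 13.7. The matching clusters of the Eomes and Myb pools correlated with this cluster at 0.841 and 0.854.

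**Figure D4:**
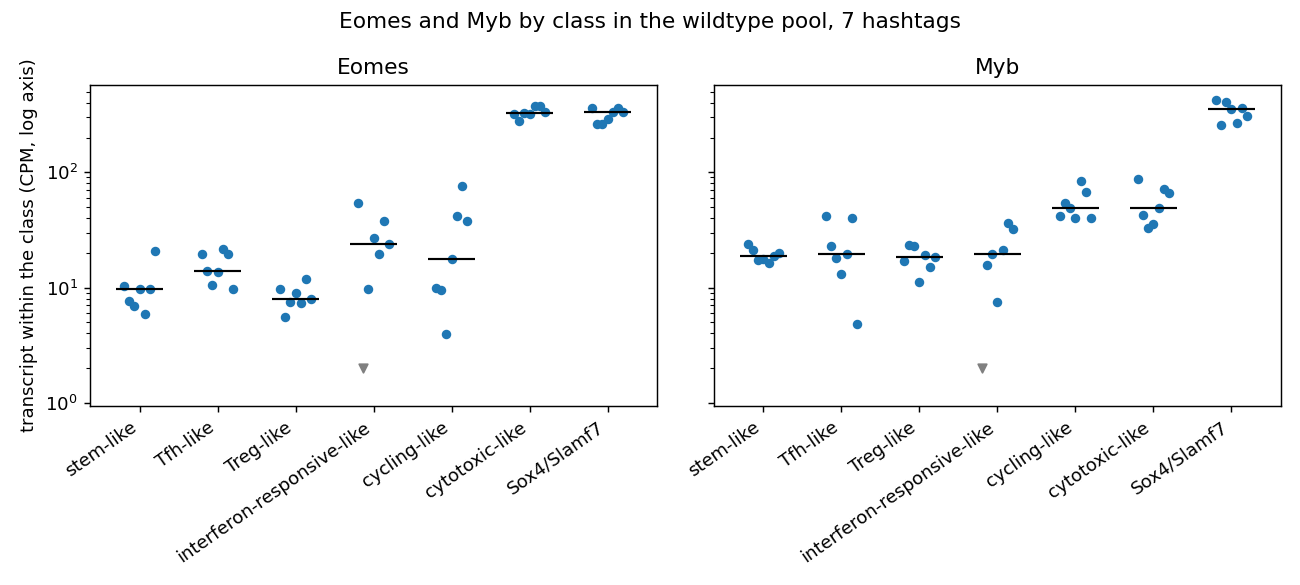
Eomes and Myb in CPM on a log axis by class in the wildtype pool, 1 point per hashtag sample with the line at the median; grey triangles at the bottom mark samples with 0 UMIs. The Sox4 and Slamf7 cluster has a median of 331 CPM Eomes and 353 CPM Myb.

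The wildtype samples differed widely in their cell classes. Stem-like cells ranged from 13.3% (HT4) to 50.7% (HT1; median 22.02%), Treg-like cells from 19.6% (HT4) to 33.5% (HT6; 31.0%) and Tfh-like cells from 1.49% (HT2) to 31.7% (HT4; 5.85%). Cytotoxic-like cells ranged from 0.789% (HT2) to 12.4% (HT4), cells led by Sox4 and Slamf7 from 0.610% (HT3) to 12.03% (HT6; median 3.74%), interferon-responsive cells from 0.628% (HT1) to 11.1% (HT7) and cycling-like cells from 1.22% to 4.61%. NK-like cells ranged from 0.199% to 3.64% and myeloid-like cells from 0% to 2.12%. Sostdc1 ranged from 3.33 (HT2) to 259 CPM (HT4), Ccl4 from 5.02 (HT2) to 231 CPM (HT4), Il21 from 2.72 (HT2) to 75.4 CPM (HT4), Gzmk from 13.0 (HT2) to 202 CPM (HT6) and Pdcd1 from 38.7 (HT2) to 274 CPM (HT4). The myeloid genes Camp (0.338 to 138 CPM), S100a8 (2.40 to 374 CPM) and Lyz2 (5.58 to 627 CPM) were among the genes with the widest ranges, and Hbb-bs ranged from 40.6 to 1159 CPM.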

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

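Both results here were found by looking across all V segments and all named genes after the data were examined, and neither was tested.

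In the library labelled Eomes knockout, the receptor segment Trav5-4 stood out from every other library. It was the segment with most UMIs in 14.39% (13.4 to 15.4) of the knockout cells with a Trav UMI, or 747 of 5192 cells. In the control and CD62L+ libraries of that pool the share of Trav5-4 was 4.25% and 3.17%, in the Myb pool it ranged from 3.16% to 5.14%, and in HT1 to HT7 it ranged from 1.77% to 3.08%. V segments were left out of the named genes and of the clustering.

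Xcl1, a chemokine gene, had opposite signs under the CD62L+ gate of the chimera pools. Its log2 ratio was −0.5044 (−0.64 to −0.37) in the Eomes pool and 0.2992 (0.16 to 0.44) in the Myb pool, and the difference was not tested. Xcl1 was read at 19.2 against 27.3 CPM in the Eomes pool and at 29.1 against 23.7 CPM in the Myb pool.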

How the results depend on the processing

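The ratio to each hashtag's background, the haemoglobin and Scrublet score alternatives, the gate comparison and the limit of 0.1 for a moved correlation were chosen after the data were examined. Of 58 comparisons of a main value with an alternative, 49 stayed within their interval or limit and 9 moved beyond it without turning.

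The log2 ratio of Eomes in its knockout comparison was −3.73, and −2.70 with HTODemux calls, −3.26 with the ratio to hashtag medians and −3.22 with the ratio to hashtag background. The log2 ratio of Myb in the library labelled Myb knockout was 0.77, and 0.48 with HTODemux and 0.45 with the ratio to medians. HTODemux kept few cells of the CD62L+ library of the Myb pool (975 in all), and the ratio to medians kept 194. The gap in Treg-like share in the Eomes pool was −16.45 percentage points, and −15.26 at resolution 1 and −17.85 with strict cells. In the Myb pool it was 13.48, and 16.07 with strict cells. The gate correlation between pools was 0.918, and 0.784 with the ratio to medians.

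A few values turned. Ighm under the gate in the Eomes pool was 0.0569 with HTODemux, effector migration there was −0.34 without Treg-like cells, and Xcl1 in the library labelled Myb knockout was −0.69 (−0.685) with T cell clusters only. The interferon-responsive share in the Eomes knockout comparison turned to −1.13 points with cells thinned before clustering. It also turned to −14.55 points with strict cells, a gap larger than the main control share of 3.23%. The class therefore held other cells there, and that turn does not compare the same cells. Relative to the median gene, the Treg list of the Eomes knockout comparison also turned, to 0.11 without Treg-like cells. The cause was not tested.

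Of 3496 values of named genes 799 moved and 2 turned, of 840 list medians, taken as plain log2 ratios, 47 moved and 1 turned, of 154 shares 41 moved and 2 turned, and of 22 correlations 2 moved. The correlation of the knockout comparisons ranged from 0.256 to 0.307. After thinning, the median log2 ratios for stem-like cells were −2.38 (Eomes) and −1.18 (Myb), and for the Sox4 and Slamf7 cluster 2.70 and 3.37.

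No paired analysis was possible for the knockout comparisons, because each group holds 1 hashtag sample. For the gate the chimera pools give a pair each, and a fit over these pairs was left out. In the wildtype pool each sample gives a cluster and its other cells as a pair, and only the direction was counted (7 of 7 samples), without a test. Because groups hold 1 sample or because HT1 to HT7 are unassigned, the comparison of Docile with Armstrong, DESeq2, counts without a filter, leaving out 1 replicate, a replicate block, the split by tissue, list tests such as camera and fry and an overlap by adjusted p were not run. The Scrublet alternative is void, since its own threshold marked almost no cell. A class absent under a clustering gave no value. Cell numbers limit the rare classes: the Tfh-like share of the Eomes knockout library rests on 5 cells.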

Other observations

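Each pool held a cluster of low depth led by nuclear RNAs such as Gm26917, Kcnq1ot1 and Macf1. Its median depth was 1283 UMIs in the wildtype pool, 1557 in the Eomes pool and 1874 in the Myb pool. Eomes stood there at 91.0, 153 and 226 CPM and Myb at 167, 159 and 221 CPM, levels above most other clusters. The wildtype pool also held a cluster of 367 cells led by the TCR signal genes Nr4a1, Il2 and Egr2, and a cluster of 193 cells led by Tmem176b, Tmem176a and Ccr6.

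In the Sox4 and Slamf7 cluster of the Eomes pool, Eomes was read at 463 CPM in control, 467 CPM in CD62L+ and 7.40 CPM (2.71 to 16.1) in knockout cells. Myb was read there at 410, 428 and 174 CPM. Hbb-bs stood at 2.39 CPM in the CD62L+ cells of the Eomes pool and between 0.485 and 0.768 CPM in the libraries of the Myb pool.

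A few patterns were weighed. All tests of the few Treg-like cells, the count of genes absent from knockout cells, the haemoglobin share and the Myb ratio at fixed cluster shares were chosen after the result was seen. In all patterns a difference between donors or sorts stays open, because each group was 1 hashtag sample, and the genotype itself stays open as an untested biological explanation.

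Few Treg-like cells were found in the library labelled Eomes knockout. A difference in depth is argued against by the thinned share of cells with a Foxp3 UMI, whose knockout to control ratio was 0.0977 (0.0698 to 0.134). CD62L+ cells under the knockout hashtag are argued against by Foxp3, at 0.0489 (0.0432 to 0.0551) of its CPM in the CD62L+ library. A general loss of clusters with few cells cannot be told apart, since the cytotoxic-like share was also far lower (0.0486% against 4.65%). The interferon-responsive share had a ratio of 1.33 (1.05 to 1.69) but turned to −1.13 points with cells thinned before clustering. The cycling-like share was less reduced (1.77% against 2.58%). Clusters 1 and 2, large in the control, also held lower shares (0.421% against 25.9% and 1.02% against 21.2%). Cluster 0 held 81.4% of knockout and 0.671% of control cells, so the other clusters together had to hold a lower share. The lower shares of clusters 1 and 2 therefore do not decide whether the loss was wider. The Sox4 and Slamf7 share had a ratio of 1.02 (0.711 to 1.47), but its knockout cells lacked much of both genes, so it decides nothing.

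The library labelled Eomes knockout leaned weakly towards the CD62L+ gate, with a correlation of 0.235 to the gate ratios of the Myb pool. The library labelled Myb knockout correlated at 0.258 with the gate ratios of the Eomes pool, so such a lean was not particular to the Eomes knockout. A slope was taken over 93 genes chosen as at least 2-fold apart between the gates of the Myb pool. The Eomes knockout log2 ratios had a slope of 0.531 (0.238 to 0.772) on these gate ratios, with the same sign for 66.7% of the genes. This slope was the test planned beforehand for CD62L+ cells under the knockout hashtag. It fell between the limits set for and against that explanation, and its interval spanned both, so the planned test was undecided. CD62L+ cells under the knockout hashtag are argued against by 9 genes that are abundant in CD62L+ cells and nearly absent from knockout cells (ratios 0.0119 to 0.0718), among them Ccl4 (1.35 against 113 CPM), Slamf7 (5.41 against 156 CPM) and Sox4 (4.37 against 73.9 CPM). Of the genes named by size, 0 of 24 lay within 20 Mb of Eomes. This argues against these genes lying on a chromosome segment carried with the floxed allele. It does not test effects of such a segment on genes elsewhere or on genes that were not named. Erythroid RNA in the control library is argued against by haemoglobin, at 0.0318% (0.0313 to 0.0324) of the control UMIs; the slope without cells holding it was 0.533, a ratio of 1, but too few cells were removed for that to test it.

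Myb was not lower in the library labelled Myb knockout. Control cells under the knockout hashtag are argued against by a median within-cluster ratio of Myb to control of 2.47 (1.63 to 2.70), above 1 in each of the 12 clusters with at least 50 cells of both libraries (1.07 to 2.77). Of the smaller clusters, the Sox4 and Slamf7 cluster stood at 379 against 419 CPM, cluster 12 at 22.6 against 28.6 CPM and cluster 11 at 26.3 against 9.85 CPM, too few cells to decide. More cells of Myb-rich clusters are argued against by a ratio of 1.84 (1.67 to 2.01) with each cluster at its control share. A wrong label, and transcript of the deleted allele read outside the deleted exon, stay open.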
